A study of Mus musculus with 6 samples.

How the data were processed

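RNA was extracted with a column kit from cultured OT-I cells and libraries were sequenced on a DNBSEQ-G400 instrument, per the labels' protocols. Samples were grouped by the genotype in their labels, 3 WT and 3 Themis cKO libraries. The labels do not say whether the replicates of a genotype came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical. Per the submitters' processing notes, HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12, DESeq2 1.4.5 and the GRCm38.p6 genome were used; the notes as used here give no role or order for them.

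The authors deposited 1 table of 854 genes with a read count per library, which is an estimated count, since 66.1% of the values are whole and the rest are not. Per the file headers the same table holds the authors' log2 fold change of cKO over WT, with a p-value and a q-value per gene. How the table's genes were selected is not given in the sources used here. The values show an empty interval: no gene has a log2 ratio of mean counts between -0.94 and 1.06, so the table holds genes that differ at least about 2-fold either way around a centre of 0.06, a factor of 1.04. The deposited p-values divided by their q-values give a whole rank within 0.02 for 71.0% of 427 genes if 16996 genes were tested, against 11.2% for the next best number. The last table gene with a q-value under 0.05 has rank 2218, so the 577 table genes under that limit are 26.0% of that rank.

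Counts were rounded to whole numbers and fitted with edgeR 4.0.16 (quasi-likelihood F-test, genotype as the only term) in R 4.3.3. Genes passing edgeR's expression filter with its smallest count of 10 were tested, 794 in all, with 60 left out. P-values were adjusted by Benjamini-Hochberg and called at 0.05. The standard error of a log2 fold change was derived from the fold change and its F statistic. The planned scaling was TMM, but TMM and DESeq2 size factors assume that most genes of a table do not change, which a table selected by fold change does not meet. After the table was seen, scaling was therefore limited to median-of-ratios factors within each genotype (genes above 10 counts), 0.944 to 1.04 over the 6 libraries, with both genotypes taken at equal depth. Fold changes thus rest on the assumption that the depths of the genotypes were alike, which the library totals over all genes, not used here, would settle. The planned scaling is reported beside the main counts.

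The count test was tested on simulated data with known changes, over 783 tested genes for the cKO against WT comparison. It called 82.2% of 90 genes changed 2-fold and 100% of 93 genes changed 4-fold, none with the wrong sign. It called 3 of 600 unchanged genes. The simulation left most genes unchanged, split the changes evenly by direction and held the genotypes at equal depth, unlike a table selected by fold change. It therefore does not give the share of false calls among the genes reported here. Replicates differed by more than sampling noise in each pair (chi-square per degree of freedom of 6.10 to 18.9), which gave no sign of a duplicated library, so all 6 were kept. This spread may be technical and does not show separate animals or cultures.

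Before the data were examined, 26 gene lists with 479 genes and the rule for named genes were fixed, and 120 of the 479 were in the table. Named genes are Themis, the 10 genes with the largest log2 fold change each way among called genes whose genotypes do not overlap, leaving out predicted genes and pseudogenes, and up to 4 members of each list with the smallest p. A result that the rule would name is not reported here. Where a list had no called member, its member with the highest mean is given. The rule asked for a mean of at least 1 CPM, which needs library totals; a mean of 10 scaled counts in the higher group took its place. Set tests against a background of other genes need unselected genes, so for lists only the members per direction and Fisher's exact test are given. For genes at 0 in a genotype the fold is a bound against 3 counts over the group, and ratios with 1 to 3 counts have exact 95% Clopper-Pearson intervals; both cover counting error only. Gene IDs were matched to RefSeq on GRCm38.p6 for coordinates, 842 of 854. For comparison with the authors' values the 6 columns were refitted in DESeq2 with a factor that centres the empty interval on 0, and the authors' standard errors were derived from their log2 values and p-values as in a Wald test. Alternatives covered the test, scaling, low-count filter, thresholds, a replicate block and each library left out. DESeq2 1.42.0, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were also used.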

Results

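Messenger RNA was profiled in OT-I cells, CD8 T cells whose transgenic T-cell receptor (TCR) recognises an ovalbumin peptide. Naive OT-I cells enriched from mouse spleen and lymph nodes were wild-type (WT) or carried a conditional knockout (cKO) of Themis, a T-lineage protein that acts downstream of the TCR. Both were cultured with IL-2 at 1 µg/ml for 3 days, and 3 libraries were sequenced per genotype. The 6 libraries form 1 comparison, which asks how the transcriptome of OT-I cells kept in IL-2 differs when Themis is deleted. The deposited table holds 854 genes rather than the whole transcriptome. Over those genes the read counts summed to 946766, 1015497 and 1054442 in WT replicates 1 to 3, and to 424605, 437437 and 424992 in cKO replicates 1 to 3. These sums are not sequencing depths, which are unknown here.

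Themis itself was lower in every cKO library. The gene (Gene ID 210757, chromosome 10, positions 28668360 to 28883820 of GRCm38.p6) had 5423 ± 418 scaled counts in WT and 1140 ± 141 in cKO (mean ± SD, n = 3 each). That is 4.76-fold lower, a log2 fold change of -2.25 with a standard error of 0.11 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 5.16e-08). The authors' deposited table gives the same log2 value, -2.25, with a q-value of 1.07e-104. The remaining counts cover the whole gene, since values per exon were not analysed here.

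**Figure D1:**
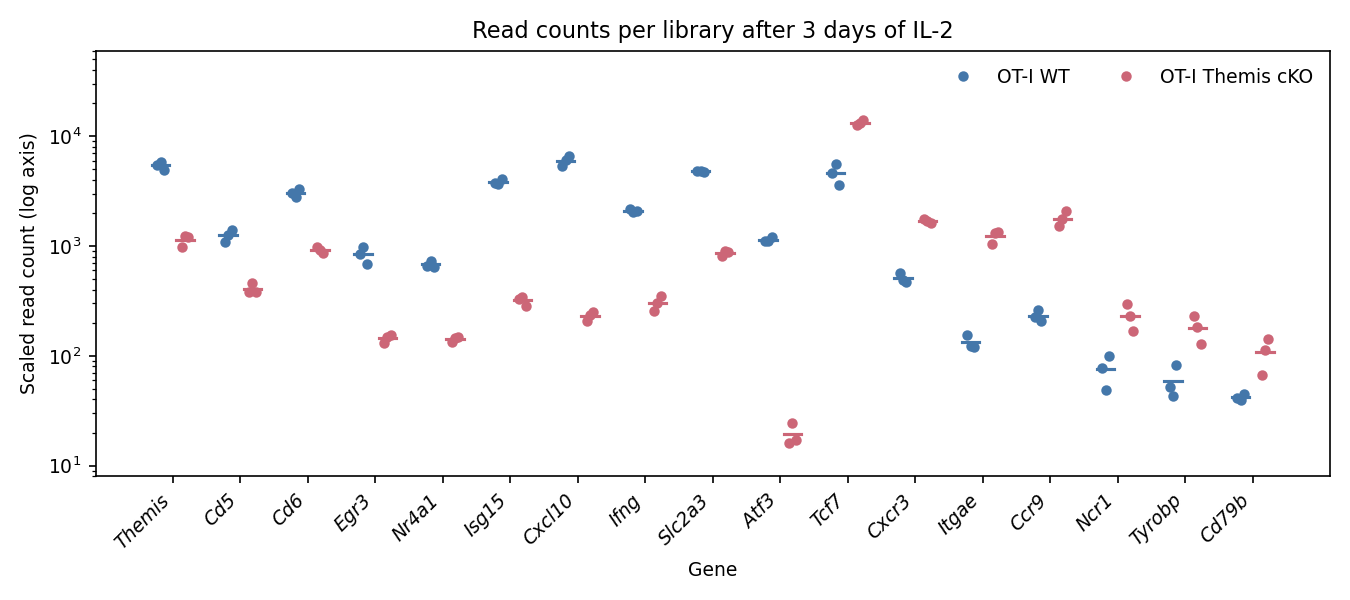
Scaled read counts (log axis) of selected named genes in the 3 WT libraries (blue) and the 3 Themis cKO libraries (red) after 3 days of IL-2; each point is 1 library and each bar a group mean. Themis fell from a mean of 5423 to 1140, while Tcf7, Cxcr3, Itgae, Ccr9, Ncr1, Tyrobp and Cd79b were higher in all cKO libraries.

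Interferon-related RNA was far lower in the Themis cKO libraries than in the WT libraries. Which cells of the cultures expressed it was not tested. Rsad2, an antiviral interferon-induced enzyme, had 5836 ± 537 scaled counts in WT and 73.7 ± 11.5 in cKO, 79.1-fold lower. Transcripts of TCR-induced factors were also lower, including Egr2, Egr3, Nr4a1 and Irf4, as were Cd5 and Cd6, surface molecules that tune TCR signalling. Transcripts of Tcf7, a transcription factor of naive and memory T cells, and of the integrin Itgae and the chemokine receptors Ccr9 and Cxcr3 were higher in cKO, as were a set of receptors typical of NK cells. Of 794 genes with enough counts to test, all 794 passed an adjusted p of 0.05, with 192 higher and 602 lower in cKO (edgeR quasi-likelihood test, Benjamini-Hochberg). The median log2 fold change was 1.45 among the genes that were higher and -1.64 among those that were lower.

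Judged by its empty fold interval, the table is a selection by fold change on these same libraries, though the sources used here do not state it. Passing the test is thus not independent evidence, and the counts are not genome-wide. With scalings that centre the table on itself, including the TMM scaling planned before the data were examined, the median log2 fold change shifted by 1.29 to 1.30 and the split became 221 higher and 218 lower with TMM, 224 and 211 with DESeq2 size factors, and 236 and 215 in DESeq2 itself. The genotypes were therefore left at equal depth, and the text below gives, with the direction of a list that was lower, how many of its members turned sign under those 3 table-centred scalings. They move all genes upward alike, so a gene higher in cKO, or lower by more than that shift, could not turn. When the adjustment was spread over the 16996 genes that the deposited p-values and q-values imply, 162 genes were higher and 558 lower.

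The genes with the lowest ratios were led by type I interferons. Ifna2, Ifna1, Ifnb1 and Ifna5 had 336, 272, 129 and 104 counts over the 3 WT libraries and 0 in all cKO libraries. Against a floor of 3 counts over the group they were at least 112-fold, 90.7-fold, 43.0-fold and 34.7-fold lower. Ifna4 had 465 counts in WT and 2 in cKO, a ratio of 232 (95% exact interval of counting error, 64.0 to 1926). The Ifna genes are near-identical copies, so their counts are uncertain one by one, while Ifnb1 (chromosome 4, 88522025 to 88522794) is a single-copy gene. Dusp8, a phosphatase of MAP kinases, had 182 counts in WT and 1 in cKO (ratio 182, interval 32.3 to 7228). The keratin gene Krt16 and the ubiquitin-like gene Ubd were at 0 in cKO, at least 16.7-fold and 15.0-fold lower. Atf3, a stress-induced transcription factor, fell from 1137 ± 56.2 to 19.3 ± 4.63 scaled counts.

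The genes with the largest increases were led by Pdlim4, which rose from 18.2 ± 8.92 to 499 ± 111 scaled counts, a log2 fold change of 4.76. Itgae, the alpha chain of the CD103 integrin, stood at 3.21 (133 ± 19.6 against 1233 ± 165) and Ccr9, a gut-homing chemokine receptor, at 2.95 (230 ± 27.7 against 1779 ± 279). The other 7 rested on WT means of 1.35 to 5.76 scaled counts: Nrg2, Dsg2, Sorcs2, Megf10, Khdc1a, Bpifb4 and Crispld2, with log2 fold changes of 2.80 to 3.50. The authors' deposited log2 values were smaller for Pdlim4, Itgae and Ccr9, at 2.87, 2.12 and 2.08. Nrg2 (3.48) and Khdc1a (3.06) stood above Pdlim4 by those values. In the authors' deposited table Sorcs2, Megf10 and Bpifb4 had log2 values of 1.39, 1.76 and 1.19, with q-values of 0.226, 0.196 and 0.427. Nrg2, Dsg2, Khdc1a and Crispld2 had q-values of 4.67e-11 to 0.0135. Megf10 was uneven, with 21.1, 22.6 and 72.7 scaled counts in cKO replicates 1 to 3. The call of Megf10 ended when the adjustment covered 16996 genes (adjusted p = 0.0652, against 0.00305 over the table and 3.89e-07 to 0.0173 under the other alternatives, edgeR and DESeq2).

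Of 26 gene lists fixed before the table was read, 19 had a tested member, 115 members in all. All 115 passed both over all tested genes and adjusted over the list alone. The empty fold interval points to a selection of the table's genes on these samples, so neither count is independent evidence. Direction was therefore tested instead, by a two-sided Fisher's exact test of higher against lower members relative to the other tested genes. This was done for the 8 lists with enough members, with Benjamini-Hochberg adjustment over the 8. The test takes members as independent, but members of the NK-type, integrated stress response and interferon-stimulated lists varied together between libraries of a genotype (mean pairwise correlation of 0.781, 0.426 and 0.362), so their p-values are too small. A listed gene outside the table was not analysed here, so counts within a list cover its selected members only.

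Interferon-stimulated genes formed the group with the most members. Of 26 genes on the list, 21 were in the table and all 21 were lower in cKO, with a median log2 fold change of -3.07; 2 of them turned sign under the table-centred scalings. The share lower exceeded that of the other genes (Fisher's exact test, adjusted p = 0.0101). Ifit3 fell from 8446 ± 813 to 519 ± 25.1 scaled counts, Isg15 from 3840 ± 243 to 320 ± 29.9 and Ifit2 from 6744 ± 138 to 767 ± 101.

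Of 19 TCR-induced early genes on the list, 10 were in the table and all 10 were lower, with 2 turning sign under the table-centred scalings. Cd69, an activation marker, fell from 9366 ± 484 to 2440 ± 77.2 scaled counts, Egr3 from 840 ± 149 to 145 ± 13.2, Egr2 from 441 ± 27.0 to 56.1 ± 14.5 and Jun from 2674 ± 164 to 976 ± 82.1, though Jun was no longer called under those scalings (adjusted p of 0.194 to 0.203; at most 5.56e-05 under the other alternatives). Of 17 inhibitory receptors and NR4A or TOX factors, 8 were in the table and all 8 were lower, with 1 turning. Lag3 fell by 4.05 on the log2 scale, and the orphan receptors Nr4a2, Nr4a3 and Nr4a1 by 3.48, 3.05 and 2.25. Of 15 effector transcription factors, 5 were in the table and all 5 were lower, with 2 turning: Irf4 fell by 2.36, Nfil3 by 2.14 and Batf3 by 2.82, while Bhlhe40, at -1.02, was among those that turned. In these 3 lists the share lower did not differ past the threshold from the rest of a table that is 75.8% lower (Fisher's exact test, adjusted p = 0.172, 0.240 and 0.344). Every tested member was already lower, and lists this small could not pass in that direction, so the test could not show an excess.

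Of 24 proximal TCR signalling genes, only 3 were in the table and all 3 were lower, of which Sla turned sign under the table-centred scalings. Cd6 (chromosome 19, 10789339 to 10830062) fell from 3042 ± 260 to 928 ± 56.5 scaled counts and its neighbour Cd5 (10718107 to 10739026) from 1247 ± 147 to 409 ± 44.1. The call of Cd5 ended under the table-centred scalings, where its log2 fold change was -0.31 to -0.32 (adjusted p of 0.0604 to 0.0713; at most 8.25e-05 under the other alternatives). Sla, an adaptor that limits TCR signalling, fell from 3547 ± 53.7 to 1471 ± 85.3. The authors' deposited table gives -1.71, -1.77 and -1.19 for these genes, with q-values of 1.69e-44, 1.31e-34 and 2.37e-11. Of 25 genes on the IL-2 receptor and STAT5 response list only Myc (-1.07) and Tnfrsf9 (-1.42) were in the table, both lower, and under the table-centred scalings Myc turned sign and the call of Tnfrsf9 ended (adjusted p of 0.230 to 0.339; at most 3.17e-05 under the other alternatives). Their deposited q-values were 1.13e-05 for Myc and 0.206 for Tnfrsf9.

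Parts of metabolic and stress lists were lower in cKO as well. Of 19 glycolysis genes, 9 were in the table and all 9 were lower, with 3 turning sign under the table-centred scalings. The glucose transporter Slc2a3 fell from 4781 ± 99.3 to 869 ± 52.4 scaled counts. The enzymes Tpi1 and Pgk1 had log2 fold changes of -1.38 and -1.11, and Aldoa fell from 44934 ± 1192 to 22460 ± 519 scaled counts; Pgk1 and Aldoa were among those that turned, and the call of Tpi1 ended under the same scalings (adjusted p of 0.250 to 0.401; at most 9.06e-06 under the other alternatives). Of 21 genes of amino acid transport and the integrated stress response, 11 were in the table and all 11 were lower, with 2 turning, and included Chac1 (-2.86), Ddit4 (-2.01) and Sesn2 (-1.69). Neither share differed past the threshold from the rest of the table (Fisher's exact test, adjusted p = 0.172 and 0.150). With every tested member lower, lists of these sizes could not pass in this direction, so the test decides nothing here. Of 21 apoptosis regulators, 4 were in the table and all 4 were lower, namely the BH3-only genes Pmaip1 (-2.04) and Bbc3 (-1.93), Bcl2a1b (-1.69, a member of a family of near-identical copies) and Casp4 (-1.04), which turned sign. Of the 11 genes on the list of dissociation stress and RNA quality, 4 were in the table and moved with these groups: Hspa1a (-2.17), Hspa1b (-1.47), Gadd45b (-1.24) and Gadd45a (100.1 ± 15.2 against 50.1 ± 8.18 scaled counts) were all lower, and both Gadd45 genes turned sign. Under those scalings the calls of Bcl2a1b (adjusted p of 0.215 to 0.320), Hspa1a (0.0993 to 0.183) and Hspa1b (0.617 to 0.722) also ended, against at most 0.00269, 0.0117 and 0.0135 under the other alternatives. Hspa1a and Hspa1b are near-identical copies of each other. No gene of the lists for G1/S, G2/M, oxidative phosphorylation, cholesterol synthesis or ribosome biogenesis was in the table.

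Of 20 cytotoxic effector genes, 3 were in the table, and the 2 tested went opposite ways. Ifng, the type II interferon, fell from 2102 ± 47.4 to 304 ± 48.2 scaled counts. Gzmm, a granzyme, rose from 88.4 ± 17.7 to 221 ± 24.8. Gzme, the other cytotoxic list member in the table, was too low to test, with 19 counts in WT and 2 in cKO (ratio 9.50, interval 2.29 to 84.1).

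Of 20 genes of naive and central memory T cells, 4 were in the table and all 4 were higher. Tcf7 rose from 4595 ± 1001 to 13253 ± 602 scaled counts, and S1pr1, the receptor for egress from lymph nodes, from 1155 ± 308 to 4246 ± 455. Actn1 and Klf2 rose by 1.23 and 1.15 on the log2 scale. The authors' deposited table gives these 4 genes smaller log2 values, 0.68, 0.87, 0.58 and 0.49, with q-values of 0.456, 0.420, 0.449 and 0.553, so none passed in the authors' own test.

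Of 26 chemokine and trafficking genes, 11 were in the table, 8 higher and 3 lower. The share higher exceeded that of the rest of the table (Fisher's exact test, adjusted p = 0.00343), a call that ended under the table-centred scalings (adjusted p of 0.159 to 0.173; 0.00311 to 0.00403 under the others). Besides Itgae and Ccr9, Cxcr3 rose from 510 ± 52.7 to 1688 ± 58.3 scaled counts. The 3 members that fell were the chemokine genes Cxcl10 (-4.70), Ccl3 (-2.93) and Ccl4 (-2.63), the last 2 named after their values were seen.

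Of 23 receptors and adaptors typical of NK cells, which activated CD8 T cells can also express, 10 were in the table and all 10 were higher. The share higher exceeded that of the rest of the table (Fisher's exact test, adjusted p = 4.56e-06). Ncr1, the NKp46 receptor (chromosome 7, 4337715 to 4345184), rose from 75.4 ± 25.4 to 232 ± 65.8 scaled counts. Tyrobp, the DAP12 signalling adaptor, rose from 59.2 ± 20.7 to 181 ± 51.8, Klri2 from 103 ± 11.7 to 257 ± 63.8 and Klrb1c from 181 ± 24.8 to 425 ± 115. The Klra members of the list are close paralogs. Some of the 13 B cell markers listed moved with them: Cd79b and Ms4a1 were higher in cKO, with log2 fold changes of 1.36 and 1.51 and cKO means of 108 and 54.3 scaled counts. The authors' deposited table gives Cd79b and Ms4a1 log2 values of 0.80 and 1.28, with q-values of 0.171 and 0.108. Neither passed 0.05 in the authors' own test, while all 10 NK-type members did. The call of Ms4a1 rests on single libraries, with adjusted p of 0.0560 without WT replicate 1, 0.0676 without WT replicate 2, 0.0529 without cKO replicate 2 and 0.122 without cKO replicate 3, against 0.0247 with all 6 and 1.70e-05 to 0.529 over all its alternatives (edgeR and DESeq2).

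Markers of other cell types were few and split in direction. Of 7 MHC class II genes, H2-Ab1 was lower (-1.73; call ended under the table-centred scalings, adjusted p of 0.339 to 0.414, at most 0.0271 under the other alternatives) and H2-Eb1 higher (1.67), and of 17 myeloid and dendritic markers, Mpeg1 was lower (-2.91) and Itgax higher (1.28). Of 7 CD4 and regulatory T cell markers, Ikzf2 was lower (-1.09, turning sign under the table-centred scalings) and Tnfrsf25 higher (1.23). Of 11 gamma-delta T cell markers, Blk and Sox13 were in the table and both were higher (2.18 and 1.28). Across cKO replicates 1 to 3, Blk (16.1, 39.4 and 59.5 scaled counts) and H2-Eb1 (26.2, 67.9 and 71.7) increased, as did Cd79b (67.5, 113 and 142). Itgax decreased (227, 138 and 102), as did Ncr1 (299, 228 and 168). Of the others, H2-Ab1 and Mpeg1 also increased, and Ikzf2, Tnfrsf25 and Sox13 peaked in replicate 2. The split in direction thus does not exclude a share of other cell types. Over 16996 genes the calls of Ms4a1, H2-Eb1, Itgax, Tnfrsf25, Blk, Sox13 and Casp4 ended (edgeR, adjusted p of 0.0508 to 0.529). Of 16 granulocyte and erythroid markers, 3 were in the table and too low to test: Cpa3, a mast cell protease, had 1 count in WT and 39 in cKO (ratio 39.0, interval 6.60 to 1579). The near-identical globin genes Hbb-bs and Hbb-bt went opposite ways, with 0 and 31 counts and 16 and 0 counts. Of 14 stromal and endothelial markers, only Madcam1 was in the table, also too low to test, at 9.61 ± 2.51 and 1.34 ± 0.591 scaled counts.

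**Figure D2:**
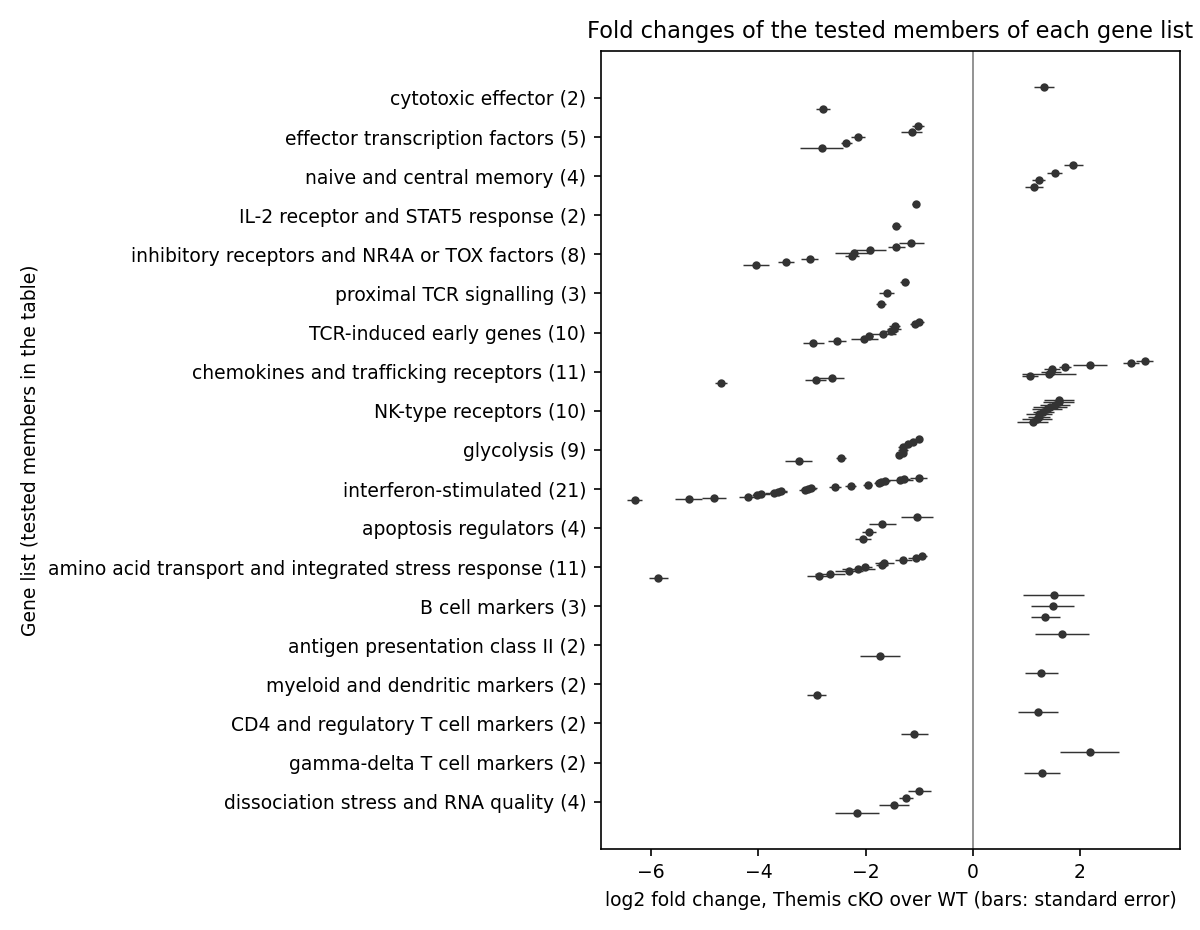
Log2 fold change (Themis cKO over WT, horizontal axis) of each tested member of the gene lists, 1 point per gene with its standard error as a bar; the number of tested members follows each list's name. All 21 interferon-stimulated members lie below 0 (2 turned sign under the table-centred scalings) and all 10 NK-type members above 0.

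The authors' deposited log2 values had the sign of the count ratio for all 854 genes. By their q-values 577 genes of the table passed 0.05, of which 107 were higher and 470 lower in cKO, and 277 did not. Of the 794 tested genes, 91.1% had a deposited log2 value nearer to 0 than that computed from the counts, and the deposited minus the computed value had a median of -0.49 for genes higher and 0.27 for genes lower in cKO. If the table was selected on its count ratios, that selection by itself favours computed values further from 0 than another estimate. Themis and Cd6 had equal values to 2 decimals in both, and the 10 NK-type members were among the genes further from 0 in the deposited table.

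**Figure D3:**
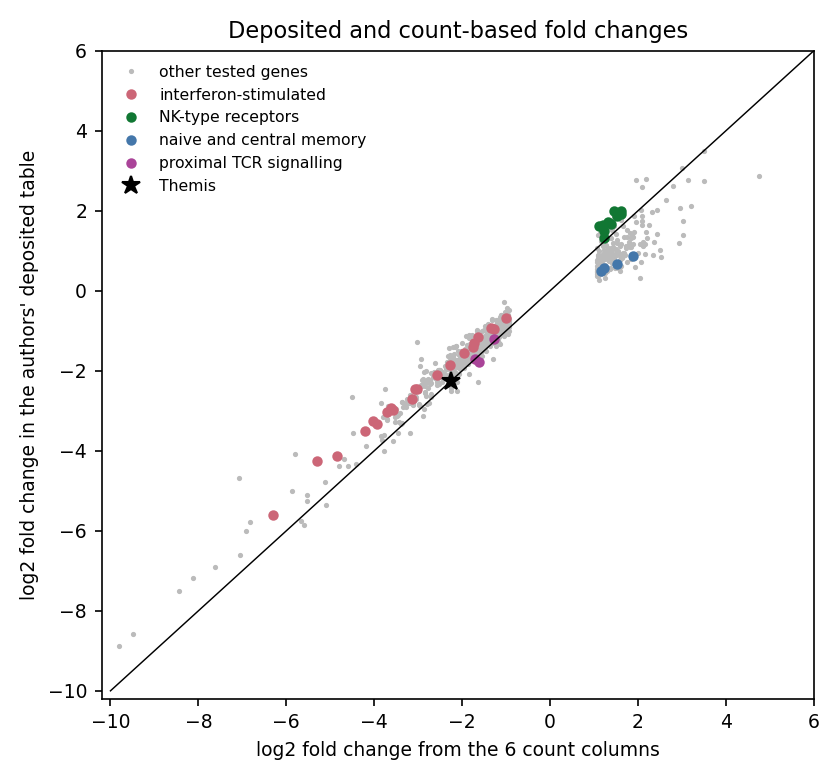
Log2 fold change (Themis cKO over WT) in the authors' deposited table (vertical axis) against that computed from the 6 count columns (horizontal axis), 1 point per tested gene, with 4 gene lists coloured and the line of equality drawn. Themis lies on the line at -2.25, the 4 naive and central memory genes lie below it and the 10 NK-type members above it.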

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

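TMM over the table, no scaling, a factor from the empty interval, DESeq2 with the main scaling and adjustment over 16996 genes were chosen as alternatives after the data were seen. The 3 table-centred scalings moved most: genes called fell from 794 to 451 in DESeq2 with its own size factors, 435 in edgeR with DESeq2 size factors and 439 with TMM, and genes lower from 602 to 215, 211 and 218. By construction they set the table's centre near 0, and Themis then stood at -0.95, -0.95 and -0.96. In the same order of scalings, log2 fold changes turned positive for Bhlhe40 (0.27, 0.27, 0.27), Myc (0.23, 0.23, 0.23), Sla (0.028, 0.028, 0.021), Pgk1 (0.19, 0.19, 0.18), Aldoa (0.30, 0.30, 0.29), Casp4 (0.25, 0.25, 0.25), Ikzf2 (0.21, 0.21, 0.20), Gadd45b (0.060, 0.059, 0.053) and Gadd45a (0.30, 0.30, 0.29). Tnfrsf9, Cd5, Jun, Tpi1, Bcl2a1b, H2-Ab1, Hspa1a and Hspa1b kept their sign but were no longer called under these 3. Under the other settings all counts of calls stayed within 1.5 times those reported: 854 genes with no filter, 796 with a stricter one, 796 with no scaling and with the interval factor, 854 in DESeq2 with the main scaling, 786 at an adjusted p of 0.01, 749 at an absolute log2 fold change of at least 1 and 720 over 16996 genes. Leaving out each library in turn gave 798 to 810 genes, 191 to 197 higher and 601 to 616 lower, and Themis between -2.32 and -2.15; among named genes it ended only calls of Ms4a1. Replicate numbers gave no sign of pairing: same-numbered WT and cKO libraries deviated with correlations of -0.004, -0.141 and -0.274 across 613 genes. Other WT and cKO libraries correlated at -0.087 to 0.218, and 3 libraries per genotype are too few to exclude pairing. With the replicate number as a block, 793 genes were called, 191 higher and 602 lower, Themis stood at -2.25 and no other call changed among the named genes and lists. Depth limits genes at or near 0 counts, whose folds are bounds. Alternatives for normalized values and set tests with camera or fry were not run, since the values are counts and the table holds no unselected genes.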

Other observations

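All tests in this part except the co-variation test of NK-type members were chosen after the values they bear on had been seen. A group of hypoxia-response genes, listed after the values were seen and so descriptive only, was lower in cKO in 18 of 18 members in the table (of 24 listed), with a median log2 fold change of -2.52; 2 members turned sign under the table-centred scalings. Vegfa, the vascular growth factor, fell from 863 ± 30.2 to 84.3 ± 2.44 scaled counts, Bnip3, a mitophagy receptor, from 3359 ± 195 to 382 ± 103, Egln3, an oxygen-sensing prolyl hydroxylase, from 2130 ± 93.0 to 259 ± 59.3 and Ndrg1 from 4320 ± 340 to 557 ± 73.5. Cytosolic and endosomal nucleic acid sensors, also listed afterwards, had 7 of 13 members in the table, all 7 lower. Zbp1 among them is also on the interferon-stimulated list, so the 2 lists overlap. In a table that is 75.8% lower, this share was not shown to differ (two-sided Fisher's exact test, unadjusted p = 0.205). A list this small could not pass in that direction. Ifih1, which encodes MDA5, fell from 2440 ± 108 to 288 ± 9.82 scaled counts and the endosomal sensor Tlr7 from 1241 ± 233 to 263 ± 12. Of 18 type I interferon genes, 7 were in the table and the 5 tested were all lower, with a median of -6.50 when the 4 genes at 0 in cKO are set at their bound.

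The table holds more genes lower than higher in cKO. A depth difference between the genotypes would move the empty fold interval away from 0 by about the table's median ratio, yet its centre lies at 0.059. This argues against depth as the cause, provided that the interval was set on values scaled over all genes, which the sources used here do not state. Of the 10 splits of the 6 libraries into groups of 3, only the real one (1 split) called as many genes, 794 against at most 0 in the others by edgeR (84 to 177 at an unadjusted p under 0.05), but 10 splits are too few for a share under 0.05, and the table's genes were selected under the real grouping, which sets this outcome. The genotype stays open as a biological explanation, and may act through any of the groups described. The labels do not say whether replicates were separate cultures. A difference between the cultures of the genotypes, in conditions or in their mix of cells, therefore cannot be told apart from the genotype here.

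The deposited log2 values and q-values differ from those the 6 count columns give, here in a DESeq2 refit with the genotypes centred on the empty interval. A single scaling factor between the genotypes would shift all genes alike, but the median offsets of genes higher and genes lower differed by -0.78, which argues against it as the only cause. Selection of the table on its count ratios would also set these offsets apart, so a factor acting beside it is not excluded. Shrinkage in the authors' test would pull values towards 0, and imprecise genes most, but all 10 called NK-type members were further from 0, and among the other 784 called genes the median ratio of deposited to refitted log2 was 0.787 where standard errors were below their median and 0.817 where they were above their 75th percentile. A single prior width set on the former, over the refit's standard errors, predicts 0.222 for the latter, a gap of 0.595 (bootstrap 95% interval over genes, 0.545 to 0.636). This argues only against shrinkage by 1 width over the refit's standard errors. Shrinkage over the authors' own standard errors, which the deposited values put at another size, was not tested and stays open for genes nearer to 0 in the deposited values. Some genes outside the NK-type list were also further from 0, which shrinkage alone would not give. Examples are Itga1 (2.80 deposited, 2.15 refitted) and Cx3cr1 (1.76 and 1.36). An earlier test, in which 3.78% of called genes (30, more than the 10 of the NK-type list) exceeded the count value by over 0.2, decided nothing. A comparison with other libraries or another model may account for the differences: the standard error implied by the deposited values was 2.003 times that of the refit (median of 354 genes), barely past the limit of 2, and 4.43 for interferon-stimulated genes, 2.87 for naive and central memory genes, 1.06 for NK-type genes and 0.754 for Themis, and no biological explanation was tested.

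NK-type transcripts were higher in cKO, and a change within the OT-I cells, which can express these receptors once activated, stays open, untested. A larger share of every other cell type would raise all their markers by 1 factor, but of the 21 tested markers of 6 lists 18 were higher and 3 lower (chi-square test of Cochran's Q across genes taken as independent, p = 2.71e-110). No gene of the table has a log2 ratio between -0.94 and 1.06, so members on both sides of 0 make this p small in advance, and it decides nothing. The 3 lower markers go against a rise of all 21 by 1 factor only if OT-I cells do not express them, which was not tested. The folds of the NK-type and B cell members were not shown to differ (the same chi-square test, p = 0.983 over 13 genes, and p = 0.925 over the NK-type members), but selection at about 2-fold narrows their range, and between the lists deviations correlated at 0.752 across the WT and -0.900 across the cKO libraries: Ncr1 had 299, 228 and 168 scaled counts and Cd79b 67.5, 113 and 142 in cKO replicates 1 to 3. A joint share of both cell types would move them together, though 3 libraries per genotype are too few to decide. A larger share of NK cells may be a candidate explanation: within genotypes the 10 members varied together across libraries, with a mean correlation of 0.781 against 0.166 at the 95th percentile of 10000 matched random lists, though it was also 0.873 for B cell and 0.878 for naive and central memory genes; its most abundant member, Fcer1g, reached 193 ± 60.9 scaled counts in WT and 558 ± 184 in cKO, and the labels name enrichment of naive cells without a sort that would exclude NK cells.

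Genes near Themis were examined for effects tied to its chromosome region. Within 10 Mb on each side, 4 of 103 protein-coding genes (3.88%) were in the table, against 3.87% elsewhere (two-sided Fisher's exact test, p = 1), which gives no sign of an excess.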
